A study of Mus musculus with 23 samples.

How the data were processed

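MicroRNA levels were measured in 23 mouse retina samples by stem-loop RT-qPCR. Per the labels, total RNA was purified with a microRNeasy kit, reverse transcribed with a megaplex pool of 522 primers, pre-amplified for 14 cycles and read with a FAM reporter. The deposited table holds quantification cycles (Cq) as the authors exported them, named as not normalized; a lower Cq means more template, and 1 cycle is about a doubling. Wells without a value are entered as undetermined. The software, threshold and baseline behind the Cq values are stated neither in the labels nor in the file header. The table holds 522 assays, all 23 samples and 10 empty columns without a name, which were not used. It holds no small RNA control assay and no assay for miR-34a, miR-451 or miR-223.

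The labels place the samples in 2 profiling sets, each with its own wild-type (WT) and double-knockout (DKO) samples. The first set has 3 WT, 3 DKO, 3 DicKO and 4 DKO_DicKO samples, and the second set has 3 WT, 3 DKO and 4 DKO_P53KO samples. In the first set the DKO samples are titled with Chx10Cre, floxed Rb and loss of p107, and the DicKO samples as floxed for Dicer1. In the second set the labels say only DKO and DKO_P53KO, which were read as the same genotype without and with loss of p53. The title of the DicKO samples names no Cre. Here "without Dicer1" means the DicKO and DKO_DicKO groups, titled as floxed for Dicer1. How complete the loss of Dicer1 was in them is not stated and was not measured. Ages, litters and whether each sample is a separate animal are not stated, so the p-values measure only the spread between samples. No value above Cq 32 occurs in the first set, whereas 196 values above Cq 32 occur in the second. In the first set, 31 assays were undetermined in all samples although each had a Cq of 30 or lower in all samples of the second set. An undetermined well in the first set is therefore not proof of a low level, although the fits entered it as a low value, the floor described below.

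An assay counted as detected at Cq 32 or lower. The log2 relative quantity of an assay was the mean Cq of the assays detected in all samples of a fit minus its own Cq, which sets the mean of those assays to the same level in each sample. This global mean was taken over 61 assays in the first set, 284 in the second and 145 over both sets, and it was the planned fallback for a table without small RNA controls. Values not detected, and detected values below it, were set to a floor, the highest scaled value of Cq 32 over the samples of the fit. The floor was −2.94 in the first set, −7.40 in the second and −4.83 over both. It raised 778 of 2011 detected values in the first set, 104 of 3248 in the second and 695 of 3044 over both, so a value at the floor need not be undetected and differences between low values are reduced. A change against a group that lies wholly at the floor is a lower bound, provided that its undetermined wells were low and had not failed. Such a change is written "at least", and its standard error is too small. An assay was tested if detected in all samples of at least 1 of the compared groups, and assays at the floor in all samples of a fit were dropped.

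Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), two-sided, with Benjamini-Hochberg adjustment over the assays tested and a threshold of 0.05 on the adjusted p. Fits within a set held all groups of the set. DKO was compared with WT within each set and over both sets with the set as a covariate, and the difference between the sets was tested with an interaction term. DKO_P53KO was compared with DKO and with WT, DicKO with WT, DKO_DicKO with DKO and with DicKO, and the 2 Dicer1 effects with each other as an interaction. The targeted transcripts of Rb, p107, p53 and Dicer1 are not measured by this assay, so the genotypes could not be checked against them. Group means of unscaled Cq were compared by two-sided exact permutation tests with adjustment over 14 tests. These replaced the planned comparison with small RNA controls and were chosen after the table was seen.

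The lists of miRNAs, the rule for naming miRNAs, the comparisons and the alternatives were written before the data were examined. The 18 lists were the miR-17~92 and miR-106b~25 clusters, the miR-106a to miR-363 cluster, p53-responsive miRNAs, E2F-linked miRNAs outside the miR-17 family, the let-7, miR-181 and miR-29 families, the sensory cluster of miR-183, miR-96 and miR-182, neural miRNAs, embryonic-type clusters, the imprinted Dlk1-Dio3 cluster, the epithelial miR-200 family, and markers of red blood cells, of white blood cells and microglia, of vessels, of muscle, and of pigment epithelium, ciliary body and lens. A list with at least 3 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of the comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were alternatives. The result of fry depends slightly on the order of the groups in the design, which was alphabetical. Named miRNAs were all tested assays of the miR-17~92 list, the 8 highest and 8 lowest changes among called assays whose samples did not overlap between the groups, and up to 4 members of each other list with a called member, called members first. Where other assays are named, this is stated. A star marks the minor arm, written with a hash sign in the table. The reference table of GRCm38.p6 was used only for neighbourhood: the genes Mir17, Mir18, Mir19a, Mir20a, Mir19b-1 and Mir92-1, 6 in all, lie on 1 chromosome within 1 kb. The table of Cq values names no genome build, so no coordinates are given.

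Alternatives were no scaling of Cq, a detection limit of Cq 35, only assays detected in every sample, no detection filter, undetected values left missing, eBayes with trend and robust estimation, fits of only the compared groups, the replicate number as a block and leaving out each sample in turn. Leaving out DKO replicate 1 and DKO_DicKO replicate 4 of the first set together was added after the data were seen. The reason was that assays taken to be background, depending little on input, came up late in both. The steps were tested on simulated data with 60 changed assays in each of 20 simulations. The changes went up and down in equal numbers, only in assays with an early mean Cq, and the noise was normal and independent between assays. Changes mostly in the same direction, as in the Dicer1 comparisons, were not simulated. The shares below need not hold for those comparisons or for late assays. At a log2 change of 1, the share of changed assays recovered was 70.2% for DKO against WT over both sets, 49.0% and 38.3% within the first and second sets, 42.5% for DKO_P53KO against DKO, 44.8% for DKO_P53KO against WT, 49.3% for DicKO against WT, 58.5% for DKO_DicKO against DKO, 55.8% for DKO_DicKO against DicKO and 36.3% for the interaction. At a log2 change of 2 the shares were, in the same order, 91.8%, 81.8%, 78.0%, 82.5%, 84.5%, 78.8%, 82.5%, 84.4% and 71.0%. Among the assays called in the simulations, 11.7% were false for DicKO against WT, above the intended 5%; the other comparisons had at most 4.83%.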

Results

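MicroRNAs were profiled in mouse retinas that lack Rb and p107 (DKO), with or without the further loss of p53 or Dicer1, and in wild-type (WT) retinas. Per the titles of the first set, Rb is floxed with Chx10Cre, whereas p107 is given as -/- and not as floxed. Rb and p107 hold back E2F-driven entry into the cell cycle, p53 is a tumour suppressor that responds to DNA damage and oncogenic stress, and Dicer1 cuts miRNA precursors into mature miRNAs. The series concerns a synthetic lethal relation between Rb, p53 and the miR-17~92 cluster in retinal progenitors. The 23 samples form 7 groups of 3 or 4 samples in 2 profiling sets. Of 522 assays, 91 to 228 were detected per sample in the first set and 307 to 350 in the second, and 153 assays were detected in no sample. With 3 or 4 samples per group the number of samples limits the precision.

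Loss of Dicer1 went with later amplification of the 61 assays detected throughout the first set, of 146 detected in all 6 samples with Dicer1. Without control RNAs, a shift of the mean Cq cannot be told apart from a different amount of total RNA. The assays detected throughout the first set had a mean Cq of 27.3 ± 1.84 (SD, n = 3) in DicKO and 24.5 ± 1.04 (SD, n = 3) in WT, a difference of 2.87 cycles (exact permutation p = 0.1, the smallest that 3 against 3 samples allow). DKO_DicKO had a mean Cq of 27.3 ± 0.896 (SD, n = 4) and DKO one of 24.8 ± 1.04 (SD, n = 3), a difference of 2.56 cycles (exact permutation p = 0.0571). In the second set DKO_P53KO amplified earlier, with a mean Cq of 22.8 ± 0.461 (SD, n = 4) against 24.4 ± 0.312 (SD, n = 3) in DKO and 24.0 ± 0.461 (SD, n = 3) in WT. The differences were −1.63 cycles from DKO (exact permutation p = 0.0286, the smallest that 4 against 3 samples allow) and −1.25 cycles from WT (exact permutation p = 0.0571). After adjustment over 14 tests none of these differences passed 0.05 (adjusted p = 0.133 for DKO_P53KO against DKO in the exact test). DKO and WT differed by 0.31 cycles in the first set and 0.37 in the second (exact permutation p = 0.5 and 0.2). All log2 changes given here are relative to the mean of these assays in each sample, so they do not hold this common shift.

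**Figure D1:**
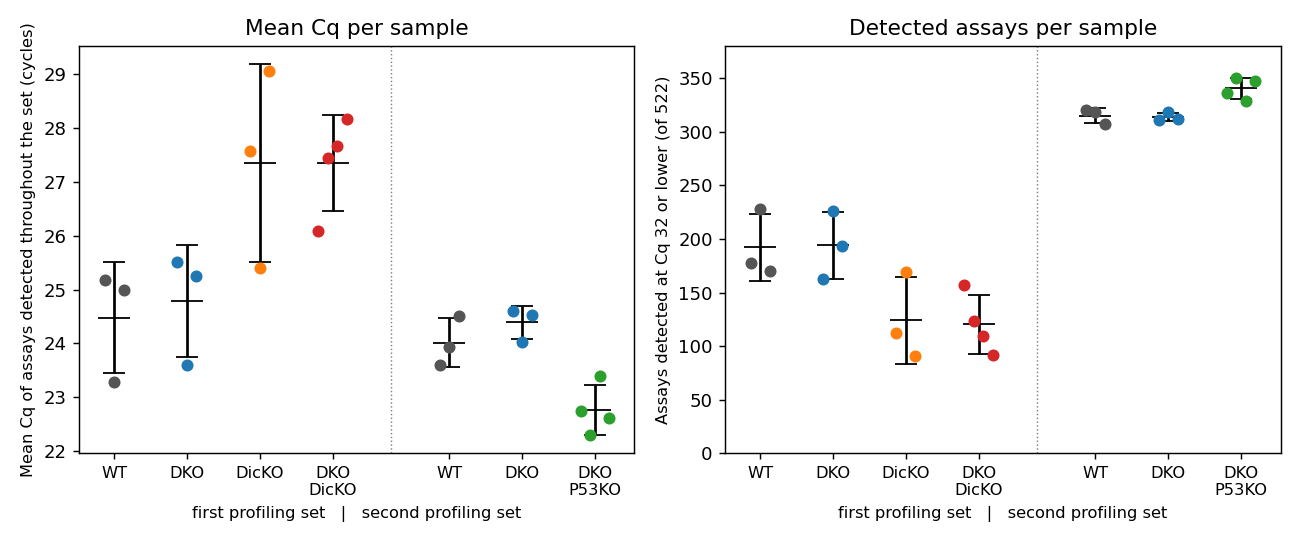
Mean Cq of the assays detected throughout each profiling set (left, cycles) and number of assays detected at Cq 32 or lower (right), per sample; points are samples, horizontal lines are group means and bars are SD. The groups without Dicer1 have group means of 27.3 cycles and 91 to 169 detected assays, and DKO_P53KO has a mean of 22.8 cycles and 329 to 350 detected assays.

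Combined loss of Rb and p107 went with lower levels of the sensory cluster of miR-183, miR-96 and miR-182. This cluster is abundant in photoreceptors and other sensory cells, and the share of these cells in the samples was not tested. Over both sets all 4 tested assays of the cluster fell in DKO against WT: miR-182 by −2.05 ± 0.26 log2 (SE, adjusted p = 6.37e-04), miR-96 by −1.96 ± 0.45 (0.0127), miR-183* by −1.89 ± 0.34 (0.00641) and miR-183 by −1.65 ± 0.41 (0.0211). The list as a whole shifted by a mean of −1.89 (adjusted p = 2.81e-04), with all 4 called also when adjusted over the list alone, and its call ended at adjusted p = 0.295 with an estimated correlation. The miR-183 effect was larger in the second set, −2.65 against −0.65 in the first, and this difference of −2.003 passed its own test (adjusted p = 0.0468). In the same comparison miR-146a, which restrains inflammatory signalling, rose by 1.83 ± 0.30 (adjusted p = 0.00413) as the called member of 3 tested white blood cell and microglia markers (list adjusted p = 0.413). Its relative miR-146b rose by 1.69 ± 0.33, and miR-497, of the miR-15/16 seed family, by 1.23 ± 0.23. MiR-100, miR-99a and miR-125b, which lie in clusters with let-7 genes, rose by 1.04 ± 0.20, 0.88 ± 0.18 and 0.72 ± 0.16. The rises of miR-100 and miR-99a were 1.58 and 1.30 in the first set but 0.50 and 0.45 in the second (interaction test, adjusted p = 0.0194 and 0.0344).

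MiR-17~92 itself, a cluster that promotes proliferation, had no called member in DKO against WT. Over both sets its 5 tested assays lay between −0.53 ± 0.23 (miR-19b) and 0.74 ± 0.44 (miR-20a), with a mean list shift of −0.02 (adjusted p = 0.613). The DKO samples of the second set were not alike, however. MiR-17 was at 3.97 and 4.21 in replicates 1 and 3 but at 1.95 in replicate 2 (WT 1.87 to 2.51), miR-20a at 4.18, 4.44 and 1.72 (WT 2.01 to 2.04) and miR-18a at −1.93, −1.78 and −4.85 (WT −5.18 to −3.91). Over all assays replicate 2 differed less from each WT sample than from the other DKO samples (SD of the Cq differences 0.624 to 0.706 against 0.894 and 0.898), but its miR-182 was at 5.16, below WT (6.97 to 7.30). The endothelial miR-126 changed by −0.95 ± 0.19 (adjusted p = 0.00677), and miR-126* had a change of −0.80 (adjusted p = 0.0211, or 0.0537 without WT replicate 3 of the first set). MiR-449, which is induced by E2F1, rose by 1.82 ± 0.37 (adjusted p = 0.00677, but 0.113 at a detection limit of Cq 35), as 1 of 3 tested E2F-linked assays (list adjusted p = 0.374). Of the p53-responsive list 1 of 4 assays was called, miR-34b-3p at 1.14 (adjusted p = 0.0218, and at most 0.0613 without WT replicate 2 or DKO replicate 1 of the first set). No member was called among 4 assays of miR-106b~25, 18 of the imprinted Dlk1-Dio3 cluster or 3 markers of pigment epithelium, ciliary body and lens. Let-7 had 1 called member of 7 and the neural list 2 of 8, and the list of 3 vessel markers had an adjusted p of 0.144. With fry the vessel and white blood cell lists passed (adjusted p = 0.0116 and 0.0314). In all, 15 assays rose and 8 fell of 167 tested with limma, and all 23 had the same sign in both sets, while 31 of the 167 differed between the sets. Without scaling the split was 0 higher and 5 lower, and of the 23 assays the 4 of the sensory cluster stayed called. Without WT replicate 2 or WT replicate 3 of the first set the count was 14 or 15.

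Within the first set alone, 14 assays rose and 9 fell in DKO among 133 tested. MiR-29a rose by 3.67 ± 0.56 (adjusted p = 0.00252), miR-24 by 1.57 ± 0.28, miR-365 by 1.31 ± 0.14 (adjusted p = 2.64e-04, but 0.490 at a detection limit of Cq 35) and miR-195 by 1.28 ± 0.23, while the sensory list had a mean of −1.05 (adjusted p = 0.175). The miR-29a effect was 0.17 in the second set, and the difference between the sets was −3.49 (adjusted p = 0.00297). In the second set the 2 called assays of 309 tested were both for miR-378, at −1.64 ± 0.29 and −1.59 ± 0.27 (adjusted p = 0.0401 for both). Both calls ended without DKO replicate 1 or 3 or any single WT sample (adjusted p up to 0.239) and with the replicate number as a block (adjusted p = 0.104 and 0.0707), and the former also with trend and robust estimation (0.0645). There the vessel list had a mean of −0.94 (adjusted p = 0.00837; adjusted p = 0.690 with an estimated correlation and 0.333 with fry), with no called member. The sensory list had a mean of −2.60 (adjusted p = 0.0403; adjusted p = 0.720 with an estimated correlation and 0.649 with fry; 0.106 without scaling), again with no called member. The p53-responsive list had a mean of 0.63 (adjusted p = 0.0403; adjusted p = 0.378 with an estimated correlation) with 0 of 6 members called, or 3 adjusted over the list alone. The miR-17~92 list had means of −0.28 in the first set (adjusted p = 0.715) and 0.34 in the second (adjusted p = 0.704). Without DKO replicate 2 of the second set the latter was 0.88 (adjusted p = 0.0480). The first set's count of 23 was 10, 9 and 7 without WT replicate 2, DKO replicate 1 and DKO replicate 3. It was 7 of 168 tested at a detection limit of Cq 35, with 4 of the 23 calls among them. In this set, with no value above Cq 32, that limit only lowers the floor, so that fewer assays are dropped for lying at it. The count was 9 over only the assays detected in every sample, 12 without DKO replicate 1 and DKO_DicKO replicate 4, and 0 without scaling. The second set's count was 0 without DKO replicate 1 or 3 or any single WT sample and without scaling, 1 with trend and robust estimation, and 12 without DKO replicate 2 and in a fit of only the compared groups.

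Loss of p53 on top of Rb and p107 went with higher levels of the whole miR-17~92 cluster. All 9 tested assays rose in DKO_P53KO against DKO, and in all 9 the 4 DKO_P53KO samples lay above the 3 DKO samples, a separation that 2 of 35 arrangements give by chance when both directions count. MiR-17 rose by 3.69 ± 0.57 log2 (SE, adjusted p = 0.00142), miR-18a by 3.64 ± 0.79 and miR-20a by 3.09 ± 0.69, or by 2.97, 2.64 and 2.22 without DKO replicate 2, the sample close to WT. MiR-19b rose by 3.07 ± 0.47 and miR-19a by 2.99 ± 0.50. The minor arms miR-17* and miR-18a* rose by 2.74 ± 0.51 and 1.81 ± 0.43. MiR-20a* was undetermined in all WT and DKO samples of the set and at Cq 22.7 to 24.4 in DKO_P53KO. Its rise of at least 6.59 takes the undetermined wells as low, and whether the assay failed in them was not tested. The smallest rise was that of miR-92, 1.79 ± 0.52 (adjusted p = 0.0236, 0.0890 without DKO replicate 2 and 0.0592 in a fit of only the compared groups). The mean shift of the list was 3.27 (adjusted p = 8.14e-05; adjusted p = 0.502 with an estimated correlation; fry p = 5.38e-04) and was 4.92 without scaling. The median shift, which depends less on miR-20a*, was 3.07. All 9 were called also when adjusted over the list alone. Against WT the mean shift was 3.57 (adjusted p = 2.18e-04; adjusted p = 0.474 with an estimated correlation). There 8 of 9 assays rose, with miR-17 at 4.90 ± 0.57 and miR-18a at 5.50 ± 0.79, and the remaining assay, miR-92, was at 0.88 ± 0.52 (adjusted p = 0.188).

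**Figure D2:**
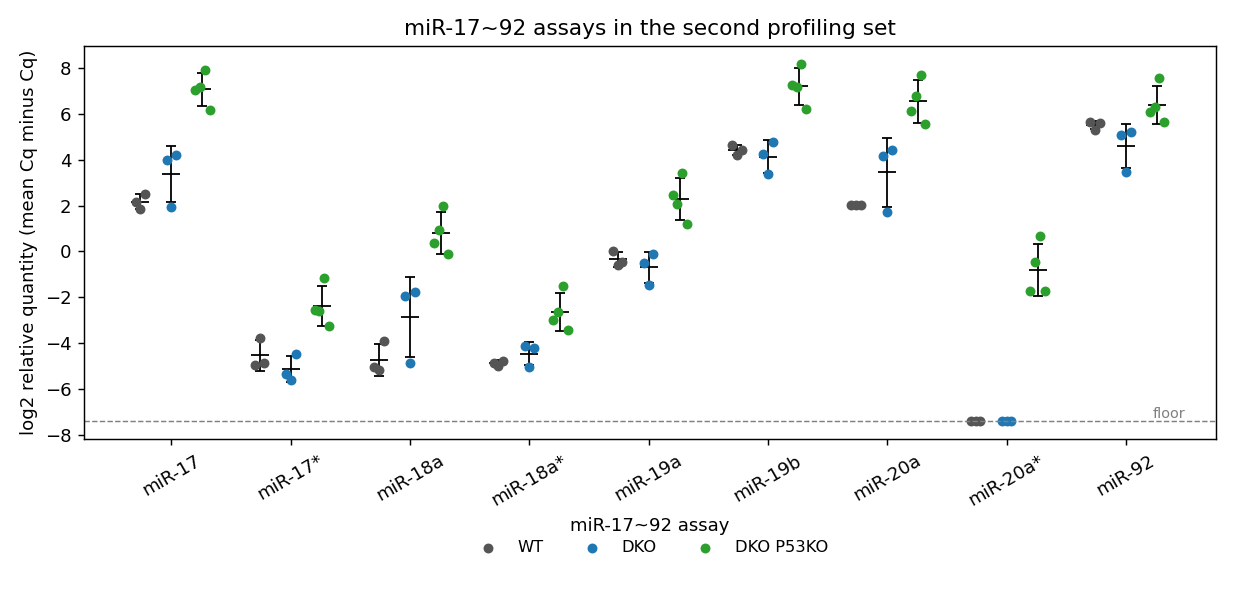
Log2 relative quantity of the 9 tested miR-17~92 assays in the second profiling set (mean Cq of the assays detected throughout minus assay Cq); points are samples, horizontal lines are group means, bars are SD and the dashed line is the floor of −7.40. In each assay the 4 DKO_P53KO samples lie above the 3 DKO samples, by a mean of 3.69 log2 for miR-17 and 1.79 for miR-92; miR-20a* is at the floor in all WT and DKO samples.

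Tested assays of the related clusters moved with miR-17~92. In DKO_P53KO against DKO, miR-106a rose by 3.75 ± 0.62 and miR-20b by 3.41 ± 0.68 (3.03 and 2.55 without DKO replicate 2). These were the 2 tested of 5 assays of the miR-106a to miR-363 cluster, so miR-18b, miR-20b* and miR-363 say nothing here. Whether the assays of miR-106a and miR-20b also read miR-17 and miR-20a was not tested. Of miR-106b~25, 4 of 5 assays rose (5 adjusted over the list alone; mean 1.88, adjusted p = 0.0179; adjusted p = 0.502 with an estimated correlation). Among them were miR-93 at 2.51 ± 0.59 (1.64 without DKO replicate 2) and miR-106b at 1.65 ± 0.38. Of the E2F-linked miRNAs 5 of 6 rose (6 adjusted over the list alone; mean 3.52, adjusted p = 0.00298; adjusted p = 0.502 with an estimated correlation). MiR-449 rose by 5.09 ± 0.94, miR-15b* by 5.03 ± 0.77, miR-449b by 4.74 ± 1.03, miR-16* by 3.17 ± 0.50 and miR-16 by 1.63 ± 0.34. The p53-responsive list rose rather than fell, with 4 of 7 members called (5 adjusted over the list alone; mean 0.94, adjusted p = 0.0269; adjusted p = 0.441 with an estimated correlation). Its called members were miR-34b-3p at 1.62 ± 0.35, miR-215 at no less than 1.32, as its DKO samples were at the floor, and miR-34b-5p and miR-34c* at 1.20 and 0.99. The call of miR-34b-5p ended without any single DKO sample (adjusted p up to 0.0980), and that of miR-34c* without DKO replicate 2 or DKO_P53KO replicate 1 or 2 (up to 0.109). Among assays with no DKO sample above the floor, miR-466d-3p rose by at least 8.34, miR-200c by at least 4.68 and miR-200b by at least 3.51, the latter bounds being 7.71 and 6.54 at a detection limit of Cq 35. The epithelial miR-200 family had 2 of 3 members higher and miR-141* lower at −1.02, or 0.61 without scaling (list mean 2.39, adjusted p = 0.216). The call of miR-141* ended without DKO replicate 1 or 3 or DKO_P53KO replicate 2 or 4 (adjusted p up to 0.0948).

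Of the assays lower in DKO_P53KO than in DKO, miR-375 changed by −5.76 ± 0.86 (adjusted p = 0.00137), miR-129 by −4.18 ± 0.90, miR-330 by −3.69 ± 0.91 and the muscle marker miR-206 by −2.92 ± 0.64. MiR-124a, the main neuronal miRNA, changed by −1.98 ± 0.31, and miR-181a and miR-181c, the 2 tested members of their family, by −2.14 ± 0.27 and −1.61 ± 0.32, although miR-181c was 0.018 without scaling. Without scaling miR-375 kept its call, and miR-129, miR-330, miR-206, miR-124a and miR-181a did not, at −3.01, −2.83, −1.29, −0.35 and −0.51. MiR-330 was −1.96 with undetected values left missing. Of the imprinted Dlk1-Dio3 cluster, which is active in neurons, 21 of 47 assays fell and 2 rose (the same counts adjusted over the list alone; mean −0.88, adjusted p = 7.78e-04; adjusted p = 0.589 with an estimated correlation and 0.0760 with fry). Without scaling, when the common shift is added to every assay, its mean was 0.66 with 15 called higher and 2 lower, and it still lay below the other assays (adjusted p = 1.72e-04). Examples are miR-409-5p at −2.84 ± 0.33, miR-329 at −2.09 ± 0.22 and miR-543 at −1.90 ± 0.28, each no longer called without scaling. The neural list had 3 of 15 members lower and 1 higher (mean −0.12, adjusted p = 0.588; 1.49 without scaling). The let-7 family had 2 of 13 members higher and 3 lower, with a mean of 0.09, a median of −0.25 and a downward test (adjusted p = 0.758), and a mean of 1.72 without scaling. In the sensory cluster 1 of 4 assays was called, miR-96 at −4.03 ± 1.24 (adjusted p = 0.0298, at most 0.0989 without DKO replicate 2 or 3, and −2.68 without DKO_P53KO replicate 3; list adjusted p = 0.204, or 6.68e-04 without scaling). Of the pigment epithelium, ciliary body and lens markers, miR-211 and miR-204 were called at −8.69 and −1.07 (list adjusted p = 0.158, or 0.0301 without scaling), the former at −3.16 with undetected values left missing. MiR-204 was 0.56 without scaling and lost its call without DKO replicate 2 (adjusted p = 0.0531), and miR-211 without any single DKO sample or DKO_P53KO replicate 1 or 3 (adjusted p up to 0.0995). Vessel markers had 2 of 4 members called higher (list adjusted p = 0.216), miR-126 at 1.55 ± 0.36 and miR-126* at 0.97, whose adjusted p of 0.0427 rose to at most 0.149 without any single DKO sample or DKO_P53KO replicate 1, 2 or 3. Of 5 white blood cell and microglia markers miR-155 was called at 1.60 (adjusted p = 0.0377, at most 0.136 without DKO replicate 2 or 3 or DKO_P53KO replicate 1 or 2). In total 65 assays were higher and 70 lower of 330 tested. Without scaling these were 197 and 3, with 68 of the 135 still called. The total was 87 without DKO replicate 2 and 85 in a fit of only the compared groups.

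Against WT, the sensory cluster was lower in DKO_P53KO in all 4 assays, as in DKO, whereas miR-126 and miR-126*, lower in DKO, were at 0.74 and 0.18 and not called. For the cluster all 4 assays were called (4 adjusted over the list alone; mean −5.91, adjusted p = 0.0473; adjusted p = 0.474 with an estimated correlation), with miR-96 at −7.09 ± 1.24 and miR-183 at −6.65 ± 1.61, or −5.73 and −4.82 without DKO_P53KO replicate 3, the sample lowest in both. MiR-182 at −5.05 and miR-183* at −4.85 lost their calls without scaling (adjusted p = 0.0748 and 0.0974) and without any single WT sample (adjusted p up to 0.0715 and 0.0847) and were −3.33 and −3.07 without DKO_P53KO replicate 3. MiR-124a changed by −2.99 ± 0.31, miR-124* by −2.05 ± 0.47 (−0.80 and not called without scaling) and miR-375 by −5.91 ± 0.86. Of the p53-responsive miRNAs 5 of 7 rose (6 adjusted over the list alone; mean 1.48, adjusted p = 0.00947; adjusted p = 0.211 with an estimated correlation), with miR-34b-3p at 2.72 ± 0.35, miR-34b-5p at 2.64 ± 0.36 and miR-34c at 1.84 ± 0.35. Of the E2F-linked miRNAs 5 of 6 rose (6 adjusted over the list alone; mean 4.06, adjusted p = 0.00595; adjusted p = 0.474 with an estimated correlation), and of miR-106b~25 4 of 5 (5 adjusted over the list alone; mean 2.44, adjusted p = 0.0103; adjusted p = 0.474 with an estimated correlation). The imprinted cluster had 18 of 46 members lower and 4 higher (mean −0.67, or 0.52 without scaling, adjusted p = 0.0242; adjusted p = 0.643 with an estimated correlation and 0.138 with fry). Of 5 white blood cell and microglia markers 3 rose (list adjusted p = 0.138): miR-142-3p by 3.37 ± 0.56, miR-146a by 2.80 ± 0.48 and miR-155 by 1.89 ± 0.53 (adjusted p = 0.0168, or 0.0589 without WT replicate 2). In total 72 assays were higher and 83 lower of 330 tested, or 159 and 12 without scaling.

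After loss of Dicer1 in otherwise wild-type retinas, miR-17, miR-106a and miR-20a had some of the lowest values relative to the global mean. MiR-17 was lower by at least 4.84 log2 and miR-106a by at least 4.64, both undetected in all 3 DicKO samples. In all 6 samples of this set with Dicer1, miR-17 was at Cq 21.8 to 23.5 and miR-106a at 21.8 to 23.6. These assays thus did not fail throughout the set, unlike the 31 assays undetermined in all its samples. A failure limited to the samples without Dicer1 was not tested. MiR-20a had a change of −4.15 ± 0.74 (adjusted p = 0.00224), miR-149 of −4.46 ± 0.92, let-7i of −3.06 or lower and miR-93 of −2.32 or lower. That of miR-19b was −2.17 ± 0.42 and that of miR-9, a neural miRNA, −1.98 ± 0.20 (adjusted p = 4.49e-05). All 5 tested miR-17~92 assays were called lower (5 adjusted over the list alone; mean −2.85, adjusted p = 0.0268; adjusted p = 0.472 with an estimated correlation; −6.17 without scaling). MiR-19a at −1.76 and miR-92 at −1.34 were the members whose calls ended without WT replicate 2 or 3 or DicKO replicate 1 or 3 (adjusted p up to 0.111 and 0.109), and miR-92 also without DicKO replicate 2. The list's adjusted p was 0.0544 without WT replicate 3, 0.0623 without DicKO replicate 2 and 0.149 with undetected values left missing (mean −1.77). Of miR-106b~25 3 of 4 assays fell (4 adjusted over the list alone; mean −1.50, adjusted p = 0.0268; adjusted p = 0.472 with an estimated correlation), and without scaling the list's adjusted p was 0.0560. Of the let-7 family 4 of 7 were called lower (list adjusted p = 0.303), but the calls of let-7b, let-7d and let-7e ended without any single WT sample or DicKO replicate 1 (adjusted p up to 0.196). MiR-15b fell by at least 1.95 and miR-181a by −1.10 ± 0.18. Relative to the global mean of the 61 assays detected throughout the set, miR-29a was higher by 3.50 ± 0.56 (adjusted p = 0.00142, but 0.63 log2 and not called without scaling). MiR-678 was higher by 3.23 ± 0.81 (adjusted p = 0.0134, at most 0.0516 without WT replicate 2 or DicKO replicate 1). In total 10 assays were higher and 38 lower of 133 tested, whereas without scaling 0 were higher and 99 lower of 161, the median of all assays then being −3.06. The count of 48 was 27, 25 and 29 without WT replicate 2, DicKO replicate 1 and DicKO replicate 3, and 25 over only the assays detected in every sample.

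Loss of Dicer1 in DKO retinas had a similar profile. MiR-17 fell by at least 4.80 log2 and miR-106a by at least 4.67, again undetected in all 4 DKO_DicKO samples, and miR-93 by at least 2.86. MiR-20a had a change of −3.26 ± 0.69 (adjusted p = 0.00387), miR-99a of −3.43 ± 0.35 and miR-100 of −2.92 ± 0.26. MiR-15b had a change of −2.77 ± 0.19, miR-9 of −2.16 ± 0.19, miR-204 of −1.48 ± 0.23 and miR-125b of −1.38 ± 0.21. Of the miR-17~92 list 3 of 5 assays were called (3 adjusted over the list alone), and its mean of −2.13 did not pass (adjusted p = 0.0786; adjusted p = 0.542 with an estimated correlation). The third called assay was miR-92 at −1.09 (adjusted p = 0.0473, above 0.05 without any single DKO sample or DKO_DicKO replicate 1 or 2, up to 0.139). The list passed without scaling (mean −5.17, adjusted p = 0.0164), with fry (adjusted p = 6.43e-04) and without DKO_DicKO replicate 3 (mean −2.57, adjusted p = 0.00706). Of miR-106b~25 3 of 4 assays fell (4 adjusted over the list alone; mean −1.53, adjusted p = 0.0717, or 3.74e-06 with fry). Relative to the global mean miR-218 was higher by 1.10 ± 0.25 (0.68 without DKO_DicKO replicate 4), miR-296 by 1.06 ± 0.21 and miR-138 by 1.02 ± 0.24, but without scaling these were −1.45, −1.50 and −1.54. Without DKO replicate 1 and DKO_DicKO replicate 4 none of the 3 was called (adjusted p = 0.0754, 0.0517 and 0.146). In total 6 assays were higher and 34 lower of 125 tested, or 1 and 98 of 157 without scaling, where the median of all assays was −2.76, and 25 were called over only the assays detected in every sample.

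The Dicer1 effects on both backgrounds had many called assays in common. Among 123 assays tested on both, 36 were called lower without Rb loss and 34 with it. Of these, 20 were shared where 9.95 would be by chance (Fisher's exact test, one-sided, p = 1.84e-05). The higher calls shared 3 of 8 and 6, where 0.39 would be by chance (Fisher's exact test, one-sided, p = 0.00336). Both comparisons used one estimate of spread per assay over all groups of the set, which can raise the number shared. They also shared the floor, so an assay could fall only as far as its level in WT or DKO allowed. MiR-17, at the floor without Dicer1 on both backgrounds, fell by at least 4.84 and 4.80. The floor can thus raise both the number shared and the correlations, and the chance numbers do not allow for it. Across these assays, which are not independent replicates, the log2 changes had a Pearson r of 0.785 and a Spearman rho of 0.675. No assay of 99 was called between DKO_DicKO and DicKO with limma (12 at an unadjusted p under 0.05), or 3 without DKO_DicKO replicate 3. The difference between the Dicer1 effects was called for 8 of 135 assays. MiR-29a differed by −4.51 ± 0.77 (adjusted p = 0.00628), since its level was higher in both DKO and DicKO than in WT of the first set. MiR-296 and miR-181a differed by 1.66 ± 0.30 and 1.39 ± 0.25, the latter no longer called without DKO replicate 1 and DKO_DicKO replicate 4 (adjusted p = 0.0525). For miR-17~92 this test says little (mean 0.72, adjusted p = 0.524, no called member), since miR-17 was at the floor in all 7 samples without Dicer1, and miR-20a and miR-19a were there in 3 and 5 of them. The count was 5 without DKO replicate 3 and over only the assays detected in every sample, and 0 without scaling.

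**Figure D3:**
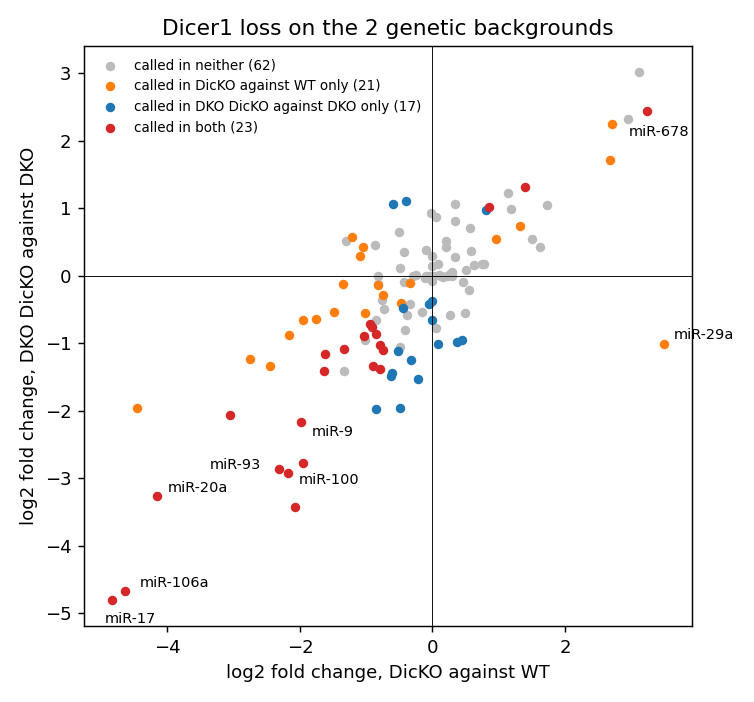
Log2 fold change of each of 123 assays after loss of Dicer1, in DicKO against WT (horizontal) and DKO_DicKO against DKO (vertical), relative to the mean of the assays detected throughout; colours show in which comparison an assay was called at an adjusted p under 0.05. In both comparisons 23 assays were called, with miR-17 and miR-106a lowest, at −4.84 and −4.64 or lower in DicKO; changes against a group at the floor are bounds.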

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

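The tests for single samples far from their group and for differences between effects follow fixed rules, and no test in this part was chosen after its result was seen. All values are log2 relative to the global mean, and no explanation was tested for them.

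In groups of 4 samples, 1 sample was set apart from the other 3 if its gap to the nearest of them, divided by the range of the group, exceeded Dixon's critical value for 4 samples. This held for 6 of 93 groups tested, and chance gives about 1 in 20. In DKO_P53KO replicate 3, miR-183 was at −6.94 against 0.06 to 0.66 in the other samples (ratio 0.921). In replicate 4 of the same group, miR-93* was at 2.63 against 3.10 to 3.17 (0.858) and miR-34c* at −1.10 against −0.45 to −0.32 (0.835). In replicate 1, let-7a was at 3.49 against 4.16 to 4.29 (0.837). In DKO_DicKO replicate 3, miR-29a was at −1.41 against 1.00 to 1.19 (0.925) and miR-204 at 3.66 against 4.55 to 4.71 (0.845).

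The effect of Dicer1 loss differed between DKO and wild-type retinas for 8 assays by limma's interaction test. The difference was 1.66 for miR-296 (adjusted p = 0.00668), 1.39 for miR-181a (0.00668), −4.51 for miR-29a (0.00628) and −1.31 for miR-365 (0.00471). It was 1.51 for miR-218 (0.0350, up to 0.107 without WT replicate 2 or 3, DKO replicate 1 or 3, DicKO replicate 1 or 3, or DKO_DicKO replicate 2). For miR-195 it was −1.39 (0.0265, up to 0.0864 without WT replicate 1 or 3, DKO replicate 1 or 3, DicKO replicate 1 or 2, or DKO_DicKO replicate 4). For miR-744 it was 1.48 (0.0131, but 0.0525 without DKO replicate 3) and for miR-497 −1.47 (0.00628, but 0.133 without DicKO replicate 3). For miR-497 and miR-365 all samples of DicKO and of DKO_DicKO lay at the floor, so the size and the direction of the difference are undecided. For miR-744 all 3 DicKO and 2 of 3 DKO samples did and no others, so its difference is at least 1.48.

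The DKO effect differed between the profiling sets for 5 named assays, given as second set minus first. The difference was −3.49 for miR-29a (adjusted p = 0.00297), −1.08 for miR-100 (0.0194), −2.02 for miR-145 (0.0283), −0.85 for miR-99a (0.0344) and −2.003 for miR-183 (0.0468). For miR-145 the effects were 0.91 in the first set and −1.12 in the second. For miR-100 they were 1.58 and 0.50 and for miR-99a 1.30 and 0.45.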

How the results depend on the processing

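The tests without DKO replicate 1 and DKO_DicKO replicate 4 of the first set, and those of the mean Cq, were chosen after the data were seen; the others were planned. Planned tests on the scale of small RNA controls and with each control assay alone were not run, because the table holds no such assays.

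Of 4807 alternative values of named miRNAs, 4237 kept their side of the threshold, 467 no longer passed, 80 newly passed and 23 changed direction with a call in the main or the alternative fit. All 23 came from using Cq without scaling, which leaves the common shift of a sample in each assay. A further 80 values changed direction without a call in either fit, so that 103 changed direction in all: 47 in leaving out 1 sample, 46 without scaling, 6 without the samples with late background assays, 2 with the replicate block, 1 at a detection limit of Cq 35 and 1 with undetected values left missing. In DKO_P53KO against DKO, let-7a then was 0.73, let-7f 0.91, miR-138 0.45, miR-128a 0.28, miR-181c 0.018, miR-141* 0.61 and miR-204 0.56. Against WT, let-7a was 0.13, miR-128a 0.026, miR-138 0.21, miR-141* 0.14 and miR-204 0.10. In DicKO against WT, miR-188-5p was −0.19, miR-124a −1.47, miR-375 −1.25, miR-376b* −1.37, miR-138 −2.01 and miR-34b-3p −2.43. In DKO_DicKO against DKO, miR-218 was −1.45, miR-296 −1.50, miR-138 −1.54, miR-96 −0.97 and miR-184 −2.56.

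Without scaling, the number of called assays was 5 in DKO against WT over both sets, 0 in the first set, 0 in the second, 99 in DicKO against WT, 99 in DKO_DicKO against DKO and 0 for the difference between the Dicer1 effects. The miR-17~92 shift in DKO_DicKO against DKO then passed at −5.17 (adjusted p = 0.0164). With only assays detected in every sample, and so fewer assays tested, the counts were 9 for DKO against WT in the first set, 25 for DicKO against WT, 25 for DKO_DicKO against DKO and 5 for the difference between the Dicer1 effects. At a detection limit of Cq 35, which only lowers the floor in the first set, the count for DKO against WT was 7. Without DKO replicate 1 and DKO_DicKO replicate 4 it was 12. For DKO against WT in the second set the count was 1 with trend and robust estimation, 1 with the replicate block and 12 in a fit of only the compared groups. With the block neither of the 2 assays called in the main fit kept its call. A fit of only the compared groups gave 85 for DKO_P53KO against DKO. With undetected values left missing, the miR-17~92 shift in DicKO against WT was −1.77 (adjusted p = 0.149). Where neither fewer samples nor fewer assays account for a change, the cause was not tested.

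With an estimated correlation the miR-17~92 shift no longer passed in DKO_P53KO against DKO (3.27, adjusted p = 0.502), DKO_P53KO against WT (3.57, 0.474) and DicKO against WT (−2.85, 0.472). The number of other lists that passed was then 0 in DKO against WT over both sets, 0 in DKO against WT in the second set, 0 in DKO_P53KO against DKO, 0 in DKO_P53KO against WT and 0 in DicKO against WT. With fry the miR-17~92 shift in DKO_DicKO against DKO passed (−2.13, adjusted p = 6.43e-04). Fry ended the calls of the imprinted cluster in DKO_P53KO against DKO and WT and, in DKO against WT in the second set, of the sensory cluster and the vessel markers. It passed lists that camera did not. These were, for DKO against WT, the vessel and white blood cell markers over both sets and the sensory and imprinted clusters in the first set (both 0.0348). In DKO_P53KO against DKO they were the miR-200 family (3.75e-04) and the pigment epithelium, ciliary body and lens markers (0.0139), and against WT the miR-200 family (4.25e-04), those markers (0.0101), white blood cell markers (0.0101) and neural miRNAs (0.0323). In DicKO against WT it was let-7 (0.00413), and in DKO_DicKO against DKO they were miR-106b~25 (3.74e-06), let-7 (0.0427) and the sensory cluster (0.0271).

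The replicate number as a block gave 20, 24 and 1 called assays for DKO against WT over both sets and in the first and second sets, 136 and 151 for DKO_P53KO against DKO and WT, 56 for DicKO against WT, 43 and 0 for DKO_DicKO against DKO and DicKO, and 10 for the difference between the Dicer1 effects. Samples with the same number had a mean residual correlation of 0.146 in the first set and 0.110 in the second, with 10 of 18 and 4 of 9 pairs above 0.1, so the numbers were not taken to pair the samples.

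Leaving out 1 sample at a time, the count ranged from 14 to 27 in DKO against WT over both sets, 7 to 19 in the first set, 0 to 12 in the second, 87 to 161 in DKO_P53KO against DKO, 109 to 172 against WT, 25 to 49 in DicKO against WT, 31 to 53 in DKO_DicKO against DKO, 0 to 3 against DicKO and 5 to 10 for the difference between the Dicer1 effects. The miR-17~92 shift ranged, in the same order, from −0.21 to 0.21, −0.42 to −0.15, −0.012 to 0.88, 2.77 to 3.58, 3.21 to 3.87, −2.996 to −2.74, −2.57 to −1.94, −0.013 to 0.78 and 0.33 to 0.91. Its adjusted p stayed at or below 2.70e-04 in DKO_P53KO against DKO and 8.30e-04 against WT. The difference in mean Cq ranged from −0.29 to 0.91 for DKO against WT in the first set, 0.16 to 0.62 in the second, −1.82 to −1.47 for DKO_P53KO against DKO, −1.46 to −1.02 against WT, 2.19 to 3.84 for DicKO against WT, 1.96 to 2.98 for DKO_DicKO against DKO and −0.97 to 0.81 against DicKO. For DKO_P53KO against DKO the exact permutation p was 0.0667 or 0.1 in all 7 runs, since fewer samples allow no smaller p. The named calls kept in each such run were 12 of 17, 7 of 21 and 0 of 2 for DKO against WT over both sets and in the first and second sets, 38 of 54 and 46 of 54 for DKO_P53KO against DKO and WT, 14 of 30 for DicKO against WT, 16 of 21 for DKO_DicKO against DKO and 4 of 8 for the difference between the Dicer1 effects.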

Other observations

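The tests of the 3 patterns weighed in this part were chosen after the result was seen, except the test of slopes; the tests of other splits of the samples were planned.

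Several lists had values that belong to no result above. In DKO_P53KO against WT, miR-29c* was called at −1.33 among 5 tested members of the miR-29 family (list adjusted p = 0.186, and its own adjusted p up to 0.111 without WT replicate 1 or 2 or DKO_P53KO replicate 1 or 3). In DKO_P53KO against DKO none of the 5 was called (list adjusted p = 0.216). The muscle marker miR-206 was the member called among 4 in both comparisons, at −2.92 and −2.90 (list adjusted p = 0.261 and 0.290), and without scaling it was −1.29 and −1.64 and not called. Of the vessel markers 0 of 4 was called with limma in DKO_P53KO against WT (list adjusted p = 0.890). The neural list there had 4 of 15 members lower and 2 higher (mean −0.28, or 0.98 without scaling; adjusted p = 0.464). The embryonic-type clusters, with 21 assays, and the red blood cell marker miR-486 had no member tested in any comparison.

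After Dicer1 loss 9 assays were undetermined in all 7 samples although detected in all 6 other samples of the first set, among them miR-17, miR-20b, miR-93 and miR-106a. A uniform fall of signal past the detection limit would have to reach 5.33 cycles or more for 5 of the 9 (miR-17, miR-20b, miR-93, miR-106a and miR-532). The assays detected throughout fell by a mean of 2.71 and at most 4.76, which goes against a uniform fall for these 5. It is not excluded, since assays with larger falls could drop out of that measure. MiR-20a, for example, had a mean Cq of 23.3 with Dicer1 and 28.7 in the 4 samples without Dicer1 where it was detected. A uniform fall stays open for the other 4, of which 3 have an expected Cq above 32 (miR-350, miR-467a and miR-667). A lower yield of the whole miR-17 seed family stays open too, since miR-106b was detected in 7 of 7 samples but at a mean Cq of 28.5 against 24.3. The 31 assays undetermined in the whole first set, although at Cq 30 or lower throughout the second, do not decide whether these 9 assays failed. Those 31 were undetermined with and without Dicer1, whereas the 9 were detected in all 6 samples with Dicer1, miR-17 at Cq 21.8 to 23.5. The labels name no separate run for the samples without Dicer1, and a failure in them alone was not tested. A faster decay of these miRNAs may also be the cause and was not tested, so the cause of the drop of miR-17 stays undecided.

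Some assays were called higher in the DicKO and DKO_DicKO retinas, although Dicer1 makes mature miRNAs. How much Dicer1 these retinas kept was not measured. Without scaling 0 of 10 stayed called higher in DicKO against WT and 0 of 6 in DKO_DicKO against DKO, but none was called lower either. The common shift, with a median of −3.06 and −2.76 over all assays, largely fixes this outcome, so whether the rise is only relative to the fall of the other miRNAs stays open. A constant background signal would give a slope of assay Cq on mean Cq near 0, but the median slope over 11 of the 13 assays was 0.98 in samples with Dicer1. Without control RNAs the mean Cq cannot be separated from the amount of total RNA. Another template that scales with total RNA would give as high a slope, so the slopes do not show that the signal is miRNA. The slopes of miR-678 and miR-34c* were lower, 0.28 and 0.34. No biological explanation was tested.

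The rise of miR-17~92 in DKO_P53KO against DKO is not accounted for by more amplifiable RNA, since the list mean was 3.27 after scaling. A lower share of the main cell type would raise the markers of every other type alike, if those types kept their proportions to each other. Of 16 tested markers 3 were called lower and 3 higher, or 0 lower and 9 higher without scaling. Between marker lists, where scaling plays no part, 3 of 6 pairs moved apart with limma. The clearest pair was white blood cell markers and those of pigment epithelium, ciliary body and lens, at 2.18 ± 0.65 (limma adjusted p = 0.0239, exact permutation adjusted p = 0.171). An exact permutation test over the 4 lists at once gave p = 0.143. Lists that move apart go against that explanation only if the other types kept their proportions, which was not tested. A change of particular cell types stays open beside a higher level of the cluster in the retinal cells themselves. Loss of p53, the labelled difference between the groups, remains a hypothesis for the cause.

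Among splits of the same samples for DKO against WT over both sets, 1 of 100, the real 1, gave as many as 23 called assays, and the highest other gave 5. The real split was also the highest, as 1 of 35, in 3 other comparisons. For DKO_P53KO against DKO it gave 135 calls (highest other 89) and a list shift of 3.27 (highest other 2.98). For DKO_P53KO against WT it gave 155 calls (highest other 99) and a list shift of 3.57 (highest other 3.21). For DKO_DicKO against DKO it gave 40 calls (highest other 32). A share of 1 of 35 is the smallest these group sizes allow. The shares were not adjusted over the tests, so chance is made less likely but is not excluded. For the difference between the Dicer1 effects 4 of 100 splits gave as many as the real 8, a share just under 0.05, but the highest other gave 17, so these calls are not set apart from what other splits give. The 10 splits of 3 against 3 samples are too few for a share under 0.05. There, the real count was 23 and the highest other 0 for DKO against WT in the first set, 2 and 1 in the second, and 48 and 0 for DicKO against WT, whose list shift was 2.85 in size and 1.18 at most in the others; in each, 1 split gave as much. For DKO_DicKO against DicKO the real count was 0, which 35 of 35 splits reach by definition, so the splits decide nothing there; the highest other was 15, for which no cause was tested.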
